A study of Solanum lycopersicum with 12 samples.

How the data were processed

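Messenger RNA was sequenced from roots of composite tomato plants (*Solanum lycopersicum*, cultivar Micro-Tom). A composite plant carries transgenic hairy roots on a shoot that was not transformed. The roots held either an empty vector (EV) or an RNAi construct against *nf-yc3* (RNAi), and the plants were mock treated or inoculated with *Rhizophagus irregularis*, a fungus that forms arbuscular mycorrhiza. The 2 constructs and 2 treatments gave 4 groups of 3 libraries, called EV_mock, EV_Ri, RNAi_mock and RNAi_Ri. All 12 libraries came from roots taken 8 weeks post inoculation at 3.2 uM phosphate, per the labels. The extraction notes name TRIzol for total RNA and a KAPA mRNA kit for the libraries. The labels give the libraries of a group as separate samples and do not say that they came from separate plants, so p-values measure the spread between these samples, which may be technical.

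The deposited table held counts of reads per gene for the 12 libraries, as whole numbers without normalization. The submitters' processing notes name FastQC, MultiQC, Trimmomatic, HISAT2, featureCounts and DESeq2, with no versions or order. Their versions, the genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, it is not known whether reads of overlapping genes on opposite strands were told apart. Separately, reads of near-identical copies may have been split or lost. Such loss may affect gene families such as the phosphate transporters, the carotenoid cleavage dioxygenases, the chlorophyll-binding proteins and the Rubisco small subunits. Their values are uncertain for that reason.

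The table had 35825 entries, of which 34658 carried Solyc gene identifiers. The other 1167 took between 0.558% and 2.07% of the counts of a library and were kept, and 106 of them passed the filter. Of all 35825 entries, 8720 had 0 counts in all libraries. Library totals ran from 17038935 to 20461032 counts. Pairs of libraries within a group had Spearman correlations across genes of 0.974 to 0.986 and a chi-square per gene of 9.3 to 99.7, where counting noise alone gives about 1, so no library was treated as a repeat of another.

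Neither the table nor the reference gene table used here (assembly SLM_r2.1, with 0 Solyc identifiers matched) pairs the identifiers with names. Gene lists were therefore used only where they held identifiers. The names in these lists were written beside published locus identifiers from general knowledge, and were not checked against an annotation. A name in the text stands for the identifier printed with it. The lists held 106 distinct identifiers, of which 93 had an entry and 85 passed the filter. The remaining 13 were not analysed here, among them those listed as PT4 and PT3, which are close relatives of PT5. The gene targeted by the construct had no identifier of which its name was certain, so its level is not reported here and the knockdown was not checked.

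Differential expression was tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16 on the deposited counts. Genes were filtered with filterByExpr at its defaults, which left 21230 genes holding at least 99.94% of the counts of a library. Libraries were scaled with TMM factors, and all 12 libraries entered a fit with group as the only term, so that the 4 groups shared an estimate of the spread. The median biological coefficient of variation was 20.7%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. There were 5 contrasts: the inoculation response in EV roots, the inoculation response in RNAi roots, the constructs compared in mock roots, the constructs compared in inoculated roots, and the interaction, which is the RNAi response minus the EV response. The standard error (SE) of a log2 fold change was taken from the F statistic. Levels are given in CPM, counts relative to the TMM-scaled library size, as mean ± SD.

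Gene lists of at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset inter-gene correlation of 0.01. The adjustment ran over 50 tests, for 10 lists in 5 contrasts, and each test was repeated with a correlation estimated from the data. The lists were mycorrhiza markers (9 genes), common symbiosis (6), strigolactone and carotenoid synthesis (14), jasmonate (8), pathogenesis-related (5), ethylene (6), iron uptake (5), photosynthesis as a mark of green tissue (7), glycoalkaloid synthesis (9) and nitrogen uptake (5). PSY3 and DXS2 belong to both the mycorrhiza and the carotenoid list. Lists for gibberellin (4), phenylpropanoids (3), phosphate starvation (2) and sugar (4) were too short for a list test. Single values were compared with exact two-sided permutation tests, which cannot give a p under 0.1 with 3 libraries against 3.

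For a group at 0 counts, a fold is given as a lower bound against 3 counts over the group, and for 1 to 3 counts as a ratio with an exact 95% counting interval. Such intervals and bounds cover counting error only. The groups, the tests, the lists, the rule for named genes and the alternative settings were fixed before the data were examined. Named genes are all members of the mycorrhiza and common symbiosis lists, up to 4 members with the smallest p of each other list called in a contrast, and members of other lists past the threshold. At most 2 further identifiers per direction and contrast are given. These are the largest changes among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries, or, where a contrast called no gene, those with the smallest p. Members of lists that were not called are named as examples chosen after their values were seen.

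Simulated counts with known changes were used to test the procedure. Genes were drawn independently, and changed genes had at least 10 expected counts in a library of mean size. Variation shared between genes was left out, so the false calls do not cover it. In the comparison of RNAi_Ri with EV_Ri (21044 simulated genes past the filter), edgeR recovered 32% of genes changed 2-fold and 77% of those changed 4-fold, with 10 false calls. DESeq2 recovered 51% and 90% with 51 false calls. In the comparison of RNAi_mock with EV_mock (21056 genes) edgeR recovered 33% and 72% with 2 false calls. For EV_Ri against EV_mock (21016 genes) it recovered 27% and 66% with 3 false calls. The alternatives were DESeq2 1.42.0, limma-voom, RLE factors, total counts without scaling factors, no filter, a minimum of 1 CPM in 3 libraries, the libraries of the compared groups alone, a minimum log2 change of 1, an adjusted p under 0.01, the replicate number as a block, an estimated inter-gene correlation, and leaving out each library in turn. Genes were filtered anew in each such fit, and a group of 2 libraries lowers that filter, so that list members can change. Leaving out RNAi_mock replicate 1 together with EV_Ri replicate 1, the marker list without members with at most 3, or at most 10, counts over a mock group, leaving out each library with the genes of the full fit kept, and the mean inoculation response over both constructs, were added after the data were seen.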

Results

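Root transcriptomes of composite tomato plants were compared in a design of 2 constructs by 2 treatments. The hairy roots carried an empty vector (EV) or an RNAi construct against *nf-yc3*, a subunit of the nuclear factor Y family of transcription factors, and were mock treated or inoculated with the arbuscular mycorrhizal fungus *Rhizophagus irregularis*. The level of the gene targeted by the construct is not reported here, so the knockdown in these libraries was not checked. Each of the 4 groups (EV_mock, EV_Ri, RNAi_mock, RNAi_Ri) had 3 libraries with 17038935 to 20461032 counts each, and 21230 genes were tested. The first principal component held 46.2% of the variance and set the mock libraries (-61.2 to -49.5) apart from the inoculated libraries (36.2 to 76.4). The second component (18.7%) ran within groups. EV_Ri replicate 1 lay at -57.3 against 38 and 52.7 for the other EV_Ri libraries, and EV_mock replicate 1 at 34.5 against -33.1 and -53.1. After group means were removed, a single axis held 38.2% of the remaining variance. RNAi_mock replicate 1 stood apart from its group on the third component, at 54.7 against -29.3 and -30.9.

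**Figure D1:**
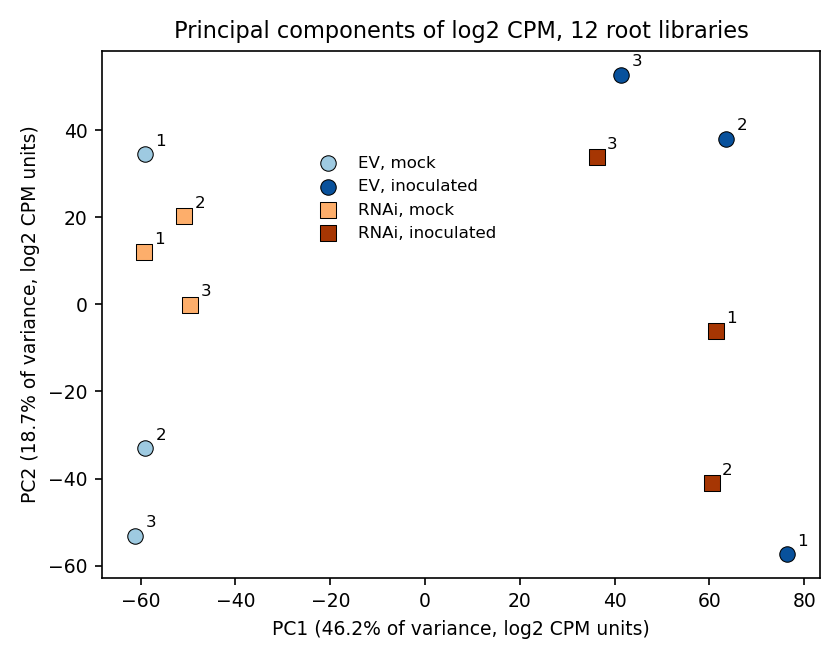
Principal components 1 (x axis, 46.2% of variance) and 2 (y axis, 18.7%) of log2 CPM, with 1 point per library, numbered by replicate and coloured by group. Mock libraries lie between -61.2 and -49.5 on component 1 and inoculated libraries between 36.2 and 76.4, while libraries of a group are spread along component 2.

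The comparison of EV_Ri with EV_mock asked how roots with the empty vector responded to the fungus. Of the 9 genes of the mycorrhiza marker list, 8 rose. PT5 (Solyc06g051860.2), a phosphate transporter, stood at 826 ± 422 CPM in EV_Ri and 1.66 ± 0.525 CPM in EV_mock (SD, n = 3), a log2 fold change of 8.94 ± 0.62 (SE, adjusted p = 1.9e-05). RAM2 (Solyc02g087500.2), an acyltransferase of the lipid pathway that feeds the fungus, rose by 9.51 ± 0.64 (adjusted p = 1.7e-05; 10.13 without EV_mock replicate 3), from 0.12 to 91.3 CPM. RAM1 (Solyc02g094340.1), a GRAS transcription factor of arbuscule development, rose by 4.91 ± 0.51 (adjusted p = 0.000269). AMT2.2 (Solyc08g067080.2), an ammonium transporter, had 0 counts in EV_mock and 147 ± 53.6 CPM in EV_Ri, at least 2930-fold higher against 3 counts over the group. STR (Solyc09g098410.2), an ABC transporter required for arbuscules, had 1 count over the EV_mock group and 8005 over EV_Ri, a ratio of 8630 with an exact 95% counting interval of 1550 to 341000.

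Smaller rises were measured for the remaining marker genes. VPY (Solyc10g081500.1), needed for entry of the fungus into root cells, rose from 41.1 to 107 CPM (log2 1.38 ± 0.22, adjusted p = 0.00541). GH3.4 (Solyc02g092820.3), an auxin-conjugating enzyme, rose from 18.8 to 519 CPM (4.79 ± 0.88, adjusted p = 0.0129), and the call was lost without EV_mock replicate 1 (adjusted p = 0.0573) or replicate 2 (adjusted p = 0.0829). DXS2 (Solyc11g010850.2), at the entry of the plastid isoprenoid pathway, rose from 20.5 to 78.5 CPM (1.94 ± 0.40, adjusted p = 0.0245). That call was lost without EV_mock replicate 2 or 3 or EV_Ri replicate 2 or 3, with adjusted p between 0.00776 and 0.13 as each library was left out, and in a fit to the 6 EV libraries alone (adjusted p = 0.075). PSY3 (Solyc01g005940.3), a phytoene synthase, did not pass (1.66 ± 0.76, adjusted p = 0.399; 2.72, adjusted p = 0.126, without EV_mock replicate 1). Adjusted over the list alone, 8 of the 9 genes rose. The list had a mean log2 change of 5.88 and a median of 4.86 (4.91 over fitted changes with AMT2.2 at its bound), was higher in inoculated roots for 9 of 9 genes, and passed the camera test (adjusted p = 6.28e-22; adjusted p = 0.0109 with an estimated correlation). An exact permutation test of the list mean per library gave p = 0.1, the smallest p that 3 libraries against 3 allow.

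**Figure D2:**
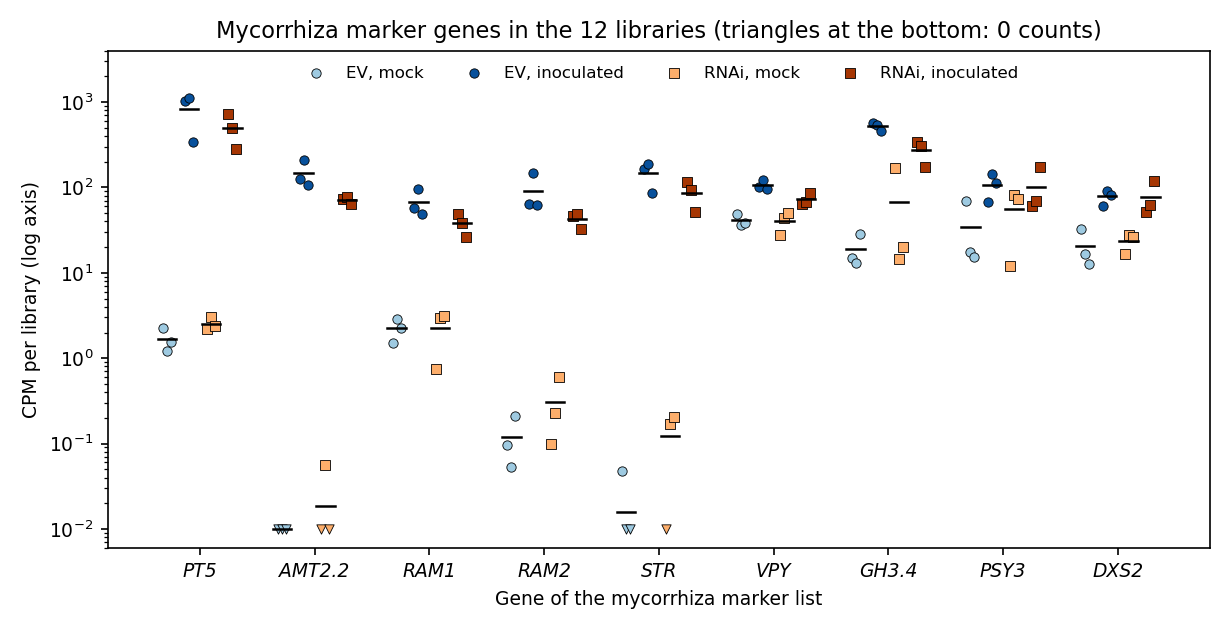
Level in CPM (log y axis) of each gene of the mycorrhiza marker list (x axis) in the 12 libraries, with 1 point per library, a bar at each group mean, and triangles at the bottom for libraries with 0 counts. PT5 averages 826 CPM in EV_Ri and 498 CPM in RNAi_Ri against 1.66 and 2.53 CPM in the mock groups.

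Across all genes, edgeR called 484 genes higher and 112 lower in EV_Ri than in EV_mock, and 2708 genes had an unadjusted p under 0.05, where 1062 would by chance alone. Among the genes called higher, 107 had at most 3 counts over the EV_mock group and 61 had 0. Solyc04g015770.1 reached 404 ± 194 CPM in EV_Ri (at least 7930-fold) and Solyc02g072370.2 reached 390 ± 163 CPM (at least 7650-fold), both from 0 counts. The largest falls were those of Solyc09g082690.3 (-4.12 ± 0.72, adjusted p = 0.00956), lost without EV_Ri replicate 2 (adjusted p = 0.0587), and Solyc02g075625.1 (-3.77 ± 0.54, adjusted p = 0.00254). DESeq2 called 797 genes higher and 300 lower, a fit to the 6 EV libraries alone called 300 and 44, and edgeR called 327 and 61 without EV_mock replicate 2. The number of falls depended on single libraries, with 55 without EV_mock replicate 3 and 65 and 64 without EV_Ri replicate 2 and 3.

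Genes of strigolactone and carotenoid synthesis were higher as a list in inoculated EV roots, with a mean log2 change of 0.82 (camera adjusted p = 0.0112), but adjusted p = 0.756 with an estimated correlation. Of its 14 genes, 2 rose over all genes tested and 2 rose adjusted over the list alone. These were DXS2 and CCD1A (Solyc01g087250.3), a carotenoid cleavage dioxygenase, which stood at 92.2 ± 9.24 CPM in EV_Ri and 52.6 ± 3.6 CPM in EV_mock (0.81 ± 0.13, adjusted p = 0.00428). Its chromosomal neighbour CCD1B (Solyc01g087260.3) had a log2 change of 0.00 ± 0.12. D27 (Solyc09g065750.3), a carotene isomerase of strigolactone synthesis, measured 1.79 ± 0.62 (adjusted p = 0.224; 0.0185 without RNAi_mock replicate 1) and PSY1 (Solyc03g031860.3) -0.62 ± 0.26 (adjusted p = 0.343), and neither passed with all libraries. MAX1 (Solyc08g062950.3) had 0 counts in all 12 libraries. PSY3 and DXS2 belong to this list and to the marker list.

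No gene of the common symbiosis list, which acts in the recognition of the fungus, passed in EV roots (0 of 6, and 0 adjusted over the list alone; mean log2 0.21, camera adjusted p = 0.461). CCAMK (Solyc01g096820.3), a calcium-dependent kinase, had the smallest unadjusted edgeR p of the list, 0.013, with 42.3 ± 5.56 CPM in EV_mock and 67.3 ± 14.3 CPM in EV_Ri (0.67 ± 0.22, adjusted p = 0.202). Log2 changes were 0.47 ± 0.45 for its target CYCLOPS (Solyc08g075760.3), -0.16 ± 0.20 for the receptor kinase SYMRK (Solyc02g091590.3), 0.12 ± 0.27 for the GRAS factor NSP1 (Solyc03g123400.1), 0.30 ± 0.16 for DELLA (Solyc11g011260.1) and -0.03 ± 0.37 for the receptor kinase LYK10 (Solyc02g089920.2), which lay near 0 and had the other sign without EV_mock replicate 1 (0.14) or EV_Ri replicate 1 (0.33).

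Among genes of the other lists, 3 passed in EV roots. NIR (Solyc10g050890.2), a nitrite reductase, fell by 1.40 ± 0.28 (adjusted p = 0.02) from 228 ± 62.1 to 86.8 ± 5.97 CPM. The gibberellin synthesis genes GA20OX1 (Solyc03g006880.3) and GA3OX1 (Solyc06g066820.3) rose by 2.67 ± 0.53 (adjusted p = 0.0207) and 3.07 ± 0.69 (adjusted p = 0.0423). NIR was not called without EV_mock replicate 2 or 3 or any 1 EV_Ri library (adjusted p 0.00914 to 0.0929 as each library was left out), and GA20OX1 was not called without EV_mock replicate 2 or EV_Ri replicate 2 (0.0115 to 0.102). GA3OX1 was not called without any 1 library other than EV_mock replicate 1 or RNAi_mock replicate 1 (0.00272 to 0.166). Without EV_mock replicate 1 the changes were 3.32 for GA20OX1 and 4.41 for GA3OX1. Both calls were also lost in a fit to the 6 EV libraries alone (adjusted p = 0.144 and 0.152), and that of GA3OX1 with total counts in place of TMM scaling (adjusted p = 0.0543). The nitrogen uptake list as a whole had a mean log2 change of -0.66 (camera adjusted p = 0.304), with 1 of 5 genes lower over all genes and 1 adjusted over the list alone.

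The remaining lists did not pass in EV roots, and no gene of them passed over all genes tested. Photosynthesis genes had a mean log2 change of -0.85 (camera adjusted p = 0.0911), with 3 of 7 lower when adjusted over the list alone, among them RCA (Solyc10g086580.2), the Rubisco activase, at 19.9 ± 7.37 CPM in EV_mock and 5.23 ± 1.94 CPM in EV_Ri. Mean log2 changes were -0.37 for ethylene (adjusted p = 0.495), 0.13 for glycoalkaloid synthesis (adjusted p = 0.856), -0.29 for jasmonate (adjusted p = 0.363) and 0.38 for pathogenesis-related genes (adjusted p = 0.639). For iron uptake the mean was 0.02 while the test pointed down (adjusted p = 0.951). The photosynthesis list was called lower without any 1 library other than EV_mock replicate 1 or 3 or EV_Ri replicate 3 (means -1.35 to -1.06, adjusted p 0.00611 to 0.0321), but in these fits the filter also let PSBS (Solyc06g060340.3) into the list. With the same 7 genes the call was left only without EV_mock replicate 2 (-0.99, adjusted p = 0.05 when rounded), EV_Ri replicate 1 (-1.22, 0.0196) or RNAi_Ri replicate 3 (-0.85, 0.0494). The jasmonate fall rested on EV_Ri replicate 1, with a list mean of 5.01 (log2 CPM) against 6.17 and 5.90 in its group and 5.89 to 6.15 in EV_mock. That list was called without EV_Ri replicate 2 (-0.53, adjusted p = 0.0265). With an estimated correlation neither list was called in those fits (lowest adjusted p = 0.575 and 0.644) or with all libraries (adjusted p = 0.981 for each). Within groups, the mean level of the glycoalkaloid list followed the axis that spread the libraries (Pearson r = 0.96, Spearman rho = 0.94, 12 libraries; permutation p adjusted over 10 lists 0.0125 for r and 0.01 for rho; r = 0.94 without the 2 outermost libraries), as did that of nitrogen uptake (r = 0.86, rho = 0.83; 0.0125 for r and 0.0175 for rho; r = 0.86 without those libraries).

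The comparison of RNAi_Ri with RNAi_mock asked the same of roots with the *nf-yc3* construct. Of the 9 mycorrhiza markers, 5 rose over all genes tested and 8 rose adjusted over the list alone. PT5 stood at 498 ± 219 CPM in RNAi_Ri and 2.53 ± 0.45 CPM in RNAi_mock (log2 7.62 ± 0.58, adjusted p = 6.36e-05). STR rose by 9.41 ± 0.63 (adjusted p = 3.95e-05; 8.82 without RNAi_mock replicate 1), RAM2 by 7.07 ± 0.56 (adjusted p = 7.77e-05; 8.01 without RNAi_mock replicate 3) and RAM1 by 4.06 ± 0.50 (adjusted p = 0.00126). AMT2.2 had 1 count over RNAi_mock and 4025 over RNAi_Ri, a ratio of 4140 with an exact 95% counting interval of 743 to 164000. VPY (0.84 ± 0.22, adjusted p = 0.114), GH3.4 (2.00 ± 0.78, adjusted p = 0.338), DXS2 (1.73 ± 0.40, adjusted p = 0.0634) and PSY3 (0.87 ± 0.75, adjusted p = 0.661; 0.24 without RNAi_Ri replicate 3) did not pass. RNAi_mock replicate 1 held 171 CPM of GH3.4 against 14.5 and 19.9 in its group, and without it GH3.4 rose by 3.99 (adjusted p = 0.00178). DXS2 was called without EV_mock replicate 1 (adjusted p = 0.0262) or RNAi_Ri replicate 1 (adjusted p = 0.0476). The list mean was 4.76 and the median 4.18, with 9 of 9 genes higher (camera adjusted p = 4.57e-19; adjusted p = 0.0109 with an estimated correlation), and the exact permutation test of its mean per library gave p = 0.1, the smallest possible.

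In RNAi roots edgeR called 267 genes higher and 85 lower after inoculation, with 2584 at an unadjusted p under 0.05, and 72 of those higher had at most 3 counts over RNAi_mock. Solyc04g015770.1 was again at 0 counts in mock roots and at 237 ± 28.3 CPM in RNAi_Ri (at least 4570-fold), and Solyc04g015800.1 went from 0 counts to 168 ± 49 CPM (at least 3240-fold). Solyc06g083160.1 fell by 3.72 ± 0.61 (adjusted p = 0.00918; 0.0554 without RNAi_Ri replicate 2 and 0.0825 with limma-voom) and Solyc12g042960.2 fell by 3.18 ± 0.68 (adjusted p = 0.047). The call of Solyc12g042960.2 was lost without any 1 library other than EV_mock replicate 1 or RNAi_mock replicate 3 (adjusted p 0.0252 to 0.216), and its change was -2.02 without RNAi_mock replicate 1 (adjusted p = 0.0751). It was not called by limma-voom (adjusted p = 0.231) or in a fit to the 6 RNAi libraries alone (adjusted p = 0.139). DESeq2 called 481 genes higher and 335 lower. EdgeR called 229, 225 and 231 genes without RNAi_mock replicate 2, RNAi_mock replicate 3 and RNAi_Ri replicate 2, of which 37, 31 and 25 were lower, and 145 were lower without RNAi_mock replicate 1.

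NIR also fell in RNAi roots, by 1.61 ± 0.28 (adjusted p = 0.0135), from 235 ± 78.7 to 77.2 ± 22.2 CPM, a call lost without RNAi_Ri replicate 1 or 2 (adjusted p 0.0108 to 0.0847 as each library was left out). CCD1A rose by 0.65 ± 0.12 (adjusted p = 0.0249), lost without RNAi_mock replicate 1 or 2 or RNAi_Ri replicate 2 or 3 (0.0207 to 0.103). In a fit to the 6 RNAi libraries alone neither NIR (adjusted p = 0.0587) nor CCD1A (adjusted p = 0.0821) was called. CCD1A was the only 1 of the 14 strigolactone and carotenoid genes to pass, with 2 adjusted over the list alone, and D27 (1.22 ± 0.61, adjusted p = 0.458) and ZDS (Solyc01g097810.3; 0.64 ± 0.31, adjusted p = 0.438), a carotene desaturase, did not. That list had a mean log2 change of 0.68 (camera adjusted p = 0.00229; adjusted p = 0.681 with an estimated correlation), or 0.31 (adjusted p = 0.071) without RNAi_mock replicate 1, whose D27 level was 1.33 CPM against 11.7 and 11.6 in its group. The common symbiosis list again had 0 of 6 genes past the test and 0 adjusted over the list alone (mean 0.16, camera adjusted p = 0.495), with CCAMK at 0.37 ± 0.22.

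For the other lists in RNAi roots, NIR was the only gene past the test over all genes. Mean log2 changes were -1.33 for pathogenesis-related genes (camera adjusted p = 0.0549, 5 of 5 lower), -0.99 for ethylene (adjusted p = 0.0698), -0.93 for nitrogen uptake (adjusted p = 0.0799), -0.51 for photosynthesis (adjusted p = 0.461), -0.36 for glycoalkaloid synthesis (adjusted p = 0.608) and 0.05 for jasmonate (adjusted p = 0.796). The iron uptake list had a mean of -0.24 and a median of 0.12 (adjusted p = 0.739). The pathogenesis-related list was called lower without any 1 library other than EV_mock replicate 1 or 3, EV_Ri replicate 3, RNAi_mock replicate 1 or RNAi_Ri replicate 2 (means -1.75 to -1.32, adjusted p 0.00613 to 0.0473; with the genes of the full fit kept, 0.0508 without RNAi_Ri replicate 3 and 0.0499 without EV_Ri replicate 3). The ethylene list was called without EV_Ri replicate 1 (-0.98, adjusted p = 0.0198) or RNAi_mock replicate 2 (-1.25, 0.0309) or 3 (-1.35, 0.0161), photosynthesis without RNAi_Ri replicate 1 (-0.93, 0.0451; -0.90, 0.0709, with the same 7 genes) and nitrogen uptake without RNAi_Ri replicate 3 (-1.25, 0.0424). None of these list calls held in the same fits with an estimated correlation (lowest adjusted p = 0.565, 0.575, 0.85 and 0.512, in that order). With all libraries, the falls of ethylene and pathogenesis-related genes leaned on RNAi_mock replicate 1 and would be smaller without it. Its ethylene list mean was 6.56 (log2 CPM), against 4.82 and 4.62 in its group. Its pathogenesis-related list mean was 8.34, against 7.12 and 6.45. Adjusted over the list alone, 1 pathogenesis-related gene was lower, the chitinase CHI3 (Solyc02g082920.3; -1.91 ± 0.59), 1 nitrogen uptake gene (NIR) and 1 photosynthesis gene, the chlorophyll-binding protein CAB3 (Solyc03g005760.1; -2.72 ± 0.62, adjusted p = 0.0647 over all genes; -3.70, adjusted p = 0.0145, without RNAi_Ri replicate 1).

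The responses of both constructs, which share no library, were set side by side. Of the genes called higher, 257 were called in EV and in RNAi roots, where independent lists of these sizes would share 6.09, and 41 were called lower in both against 0.448. Of the 650 genes called in either, 635 had the same sign in both and 0 were called in opposite directions. Across all genes, which are not independent replicates, log2 fold changes had a Pearson correlation of 0.81 and a Spearman correlation of 0.43.

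**Figure D3:**
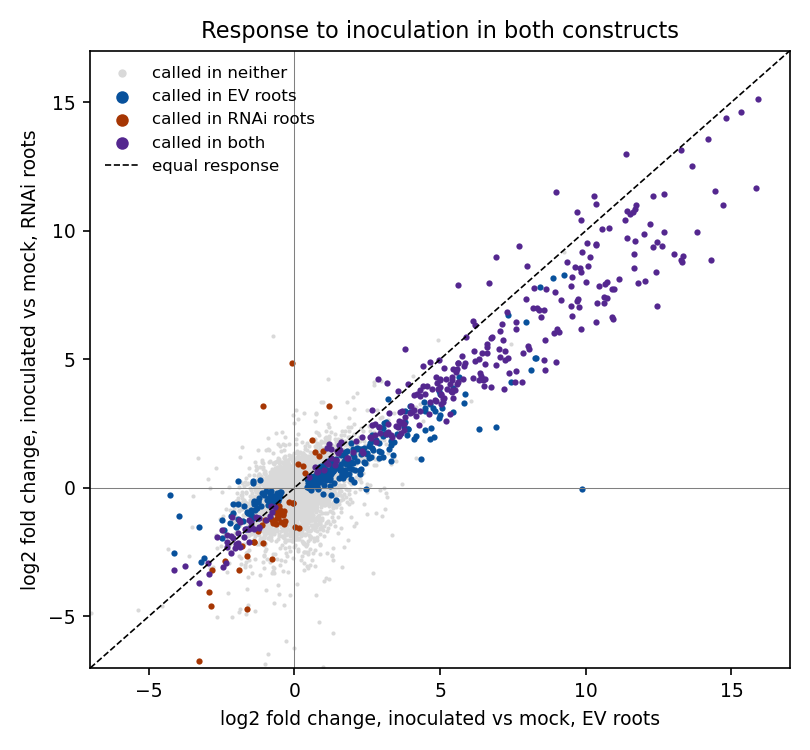
Log2 fold change of inoculated against mock roots in RNAi roots (y axis) and EV roots (x axis), with 1 point per gene, coloured by the construct in which it was called, and a dashed line where both are equal. Among the genes called in either construct, 635 of 650 have the same sign in both.

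The comparison of RNAi_mock with EV_mock asked what the construct did without the fungus. Of the markers, PT5 stood at 2.53 ± 0.45 CPM in RNAi_mock and 1.66 ± 0.525 CPM in EV_mock (0.59 ± 0.52, adjusted p = 1), RAM1 at 2.27 ± 1.32 and 2.23 ± 0.69 CPM (0.02 ± 0.49, adjusted p = 1) and VPY at 40.5 ± 11.5 and 41.1 ± 6.59 CPM (-0.02 ± 0.22). The last 2 lay near 0 and changed sign without single libraries (lowest -0.28 for RAM1 and highest 0.19 for VPY). GH3.4 stood at 68.4 ± 88.8 and 18.8 ± 8.29 CPM (1.87 ± 0.78, adjusted p = 1), with 171 CPM in RNAi_mock replicate 1 and a difference of -0.12 without it. PSY3 stood at 55.8 ± 38 and 34.1 ± 30.7 CPM (0.71 ± 0.75, or 1.77 without EV_mock replicate 1, adjusted p = 0.677). The genes nearest to a call were Solyc07g063830.3 (10.6 ± 0.586 against 26.8 ± 3.96 CPM, -1.34 ± 0.16) and Solyc10g006640.3 (6.27 ± 0.627 against 16 ± 2.09 CPM, -1.35 ± 0.16), both at adjusted p = 0.053, and Solyc08g007960.1, at 0 counts in EV_mock and 15.3 ± 10.4 CPM in RNAi_mock (at least 300-fold, adjusted p = 0.0854). For Solyc07g063830.3 and Solyc10g006640.3 it was EV_mock that stood apart, as inoculated roots of both constructs lay near RNAi_mock. Solyc07g063830.3 was at 11.8 ± 1.46 CPM in EV_Ri and 13.1 ± 1.94 in RNAi_Ri, and Solyc10g006640.3 at 5.89 ± 0.781 and 7.07 ± 0.608. EdgeR called 0 genes, with 596 at an unadjusted p under 0.05 where chance alone gives 1062. DESeq2 called 19, and limma-voom 2, which were Solyc10g006640.3 and Solyc07g063830.3 (adjusted p = 0.0479). Without the low-count filter edgeR called these and Solyc08g007960.1 (adjusted p = 0.0467), and without RNAi_mock replicate 1 it called 1 gene, Solyc04g071990.3 (1.68, adjusted p = 0.00777), which was singled out after its value was seen.

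With all 12 libraries no list passed between constructs in mock roots, and 0 genes of any list passed, also adjusted over the list alone. Pathogenesis-related genes had the smallest list p, with a mean log2 difference of 0.85 and 5 of 5 higher in RNAi_mock (camera adjusted p = 0.0549). PR1B1 (Solyc00g174340.2), a marker of salicylic acid defence, stood at 1830 CPM in RNAi_mock replicate 1 against 411 and 361 in the other libraries of that group. The pathogenesis-related list mean of that library was 8.34 (log2 CPM), against 7.12 and 6.45 in its group and 5.82 to 6.81 in EV_mock. Without that library the list difference would be smaller. The marker list had a mean of 0.46 (adjusted p = 0.0698). Means were 0.02 for common symbiosis (adjusted p = 0.991), 0.34 for ethylene (0.638), 0.23 for glycoalkaloid synthesis (0.705), 0.14 for iron uptake (0.856), -0.15 for jasmonate (0.401), -0.30 for photosynthesis (0.321) and 0.13 for strigolactone and carotenoid synthesis (0.929). For nitrogen uptake the mean was 0.05 while the test pointed down (0.904). List calls in mock roots depended on single libraries and on the preset correlation, and none held in the same fits with an estimated one. Pathogenesis-related genes were called higher in RNAi_mock without any 1 library other than EV_mock replicate 1 or 2, EV_Ri replicate 3 or RNAi_mock replicate 1 (means 0.84 to 1.28, adjusted p 0.00154 to 0.0498; with the genes of the full fit kept, 0.0593 without RNAi_Ri replicate 1 and 0.0499 without EV_Ri replicate 3), but with an estimated correlation the lowest adjusted p was 0.51 (adjusted p = 0.756 with all libraries). The marker list was called higher without RNAi_mock replicate 1 (0.68, adjusted p = 0.00226), EV_Ri replicate 2 (0.46, 0.0391) or RNAi_Ri replicate 3 (0.46, 0.0473), glycoalkaloid synthesis without EV_mock replicate 1 (0.90, 0.0386) and strigolactone and carotenoid synthesis without RNAi_mock replicate 1 (0.50, 0.0362). Photosynthesis was called lower without EV_mock replicate 2 (-0.67, 0.00869), RNAi_mock replicate 1 (-0.72, 0.0163) or RNAi_Ri replicate 3 (-0.50, 0.0446), but only with PSBS, which the filter let into the list in these fits. With the same 7 genes none of the 3 calls was left (-0.44, 0.104; -0.47, 0.19; -0.30, 0.162). With an estimated correlation the lowest adjusted p of these calls were 0.384 for the markers, 0.932, 0.552 and 0.657, in that order.

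The comparison of RNAi_Ri with EV_Ri asked whether colonised roots differed with the construct. All 9 mycorrhiza markers had lower fitted values in RNAi_Ri, and the list passed the camera test with a mean log2 difference of -0.67 and a median of -0.76 (adjusted p = 7.42e-05), but adjusted p = 0.29 with an estimated correlation. AMT2.2 stood at 71.9 ± 6.5 CPM in RNAi_Ri and 147 ± 53.6 CPM in EV_Ri (-1.03 ± 0.26), and was the only 1 of the 9 to pass adjusted over the list alone (edgeR, adjusted p = 0.032). None passed over all genes tested. Differences were -1.10 ± 0.39 for RAM2, -0.82 ± 0.42 for RAM1, -0.76 ± 0.37 for STR, -0.73 ± 0.43 for PT5, -0.56 ± 0.22 for VPY and -0.93 ± 0.76 for GH3.4. Those of PSY3 (-0.08 ± 0.74) and DXS2 (-0.01 ± 0.38) lay within their error and changed sign without single libraries, for PSY3 without EV_Ri replicate 2 (0.17) or RNAi_Ri replicate 1 (0.20) or 2 (0.13), with -0.71 without RNAi_Ri replicate 3, and for DXS2 without EV_Ri replicate 2 (0.12) or 3 (0.03) or RNAi_Ri replicate 1 (0.22) or 2 (0.12). As each library was left out, the differences ran from -1.31 to -0.57 for RAM2, -1.21 to -0.70 for AMT2.2 and -1.04 to -0.48 for RAM1. Each of these was weakest without EV_Ri replicate 2. The ranges were -1.02 to -0.48 for STR, -1.10 to -0.44 for PT5, -0.70 to -0.44 for VPY and -1.10 to -0.69 for GH3.4. An exact permutation test of the list mean gave p = 0.1, the smallest possible.

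**Figure D4:**
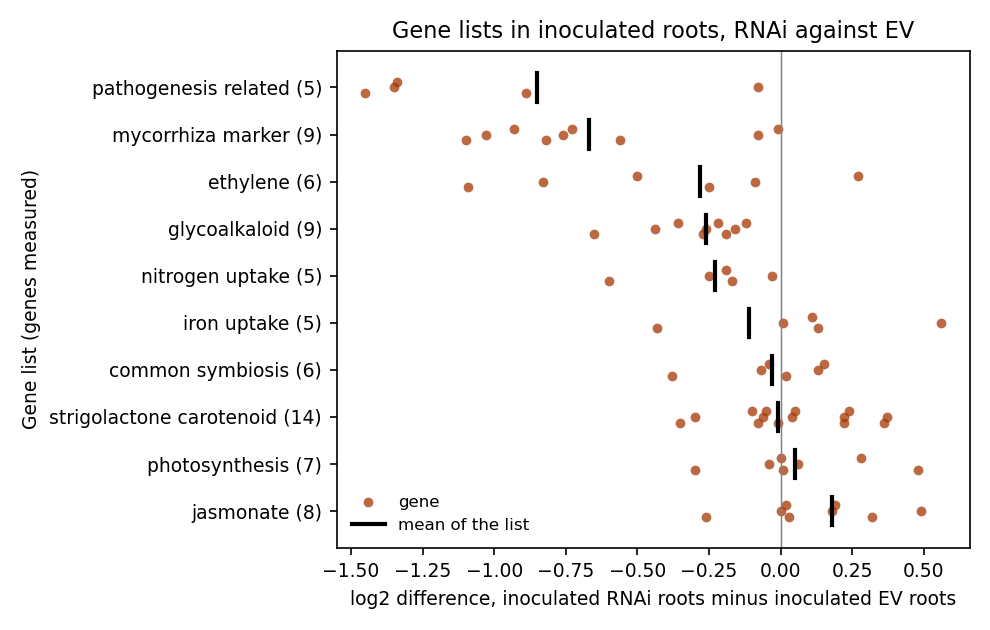
Log2 difference between inoculated RNAi and inoculated EV roots (x axis) for each gene of the 10 lists tested (y axis, with the number of genes), with a bar at the mean of each list. The mycorrhiza markers have the mean -0.67, with 9 of 9 genes below 0, and the common symbiosis genes -0.03. All genes are also below 0 for glycoalkaloid synthesis (9 of 9) and pathogenesis-related genes (5 of 5).

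Over all genes, edgeR called 0 between RNAi_Ri and EV_Ri, with 739 at an unadjusted p under 0.05 where chance alone gives 1062. DESeq2 called 8 and limma-voom 0, and edgeR called 25 without RNAi_Ri replicate 1. The smallest p belonged to Solyc04g082120.3 (12 ± 1.88 against 27.9 ± 4.98 CPM, -1.22 ± 0.22), Solyc01g106470.3 (3.4 ± 0.109 against 6.39 ± 0.771 CPM, -0.91 ± 0.17) and Solyc12g027540.2 (23.7 ± 8.83 against 4.07 ± 1.68 CPM, 2.54 ± 0.47), each with adjusted p = 1 in edgeR. The other lists did not pass and held 0 called genes, also adjusted over the list alone. Their mean log2 differences were -0.85 for pathogenesis-related genes (camera adjusted p = 0.0549), -0.28 for ethylene (0.461), -0.26 for glycoalkaloid synthesis (0.495), -0.11 for iron uptake (0.816), 0.18 for jasmonate (0.26), -0.23 for nitrogen uptake (0.321) and 0.05 for photosynthesis (0.917). Common symbiosis had a mean of -0.03 and a median of 0.01 (0.904), and strigolactone and carotenoid synthesis a mean of -0.01 while the test pointed up (0.817). By mean log2 CPM, all genes were lower in RNAi_Ri for glycoalkaloid synthesis (9 of 9), ethylene (6 of 6) and pathogenesis-related genes (5 of 5). A shared sign was therefore not particular to the markers. Pathogenesis-related genes were called lower in RNAi_Ri without EV_mock replicate 2, EV_Ri replicate 1, RNAi_Ri replicate 3 or any 1 RNAi_mock library (means -1.47 to -0.85, adjusted p 0.0111 to 0.048; with the genes of the full fit kept, 0.0556 without RNAi_mock replicate 1). Ethylene was called lower without EV_Ri replicate 1 (-0.86, adjusted p = 0.0198), nitrogen uptake lower without RNAi_Ri replicate 3 (-0.55, 0.0473) and jasmonate higher without EV_Ri replicate 2 (0.42, 0.00153). None of these calls held in the same fits with an estimated correlation (lowest adjusted p = 0.575, 0.575, 0.515 and 0.582, in that order). The pathogenesis-related list mean was 7.78 (log2 CPM) in EV_Ri replicate 3, against 5.59 and 7.11 in its group and 5.23 to 6.41 in RNAi_Ri. Without that library the fall would be smaller. The jasmonate rise rested on EV_Ri replicate 1, with a list mean of 5.01 against 6.17 and 5.90 in its group and 5.71 to 5.98 in RNAi_Ri.

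The interaction tested whether the response to inoculation itself differed between constructs. The marker list had a lower response in RNAi roots, with a mean log2 difference of -1.12, a median of -1.18 and 9 of 9 genes negative (camera adjusted p = 7.42e-05; adjusted p = 0.29 with an estimated correlation). No marker passed singly, also adjusted over the list alone. The fitted differences were -2.44 ± 0.98 for RAM2 (-3.06 without EV_mock replicate 3 and -1.49 without RNAi_mock replicate 3), -1.32 ± 0.67 for PT5, -0.84 ± 0.65 for RAM1 and -0.54 ± 0.31 for VPY. GH3.4 measured -2.79 ± 1.09, with RNAi_mock replicate 1 at 171 CPM, and -0.80 without that library. The fitted values of AMT2.2 and STR rest on 0 to 7 counts over a mock group, and without them the remaining 7 genes had a mean of -1.05, with 7 of 7 negative (camera p = 0.000647, unadjusted; p = 0.0308, unadjusted, with an estimated correlation). RAM2 also had few counts, 7 over EV_mock and 18 over RNAi_mock. Without these 3 genes the mean was -0.94, with 6 of 6 negative (camera p = 0.00495, unadjusted; p = 0.0384, unadjusted, with an estimated correlation). For all 9 genes the unadjusted camera p was 5.28e-06, or 0.0227 with an estimated correlation, so the shorter lists gave weaker results. The adjusted p of 0.29 is the value for all 9 genes over the 50 tests.

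The pathogenesis-related list also passed for the interaction with the preset correlation (camera adjusted p = 0.00813), but had adjusted p = 0.756 with an estimated correlation. Its mean log2 difference was -1.70 and its median -2.17, with 5 of 5 genes negative. Of 200 relabellings of the libraries, 19 gave an interaction of this list as large, so chance is not excluded. PR1B1 averaged 399 ± 257, 430 ± 321, 869 ± 836 and 158 ± 99 CPM in EV_mock, EV_Ri, RNAi_mock and RNAi_Ri. Interaction values were -2.65 ± 0.99 for PR4 (Solyc01g097240.3), -2.57 ± 1.27 for PR1B1, -2.47 ± 0.82 for CHI3 and -1.45 ± 0.95 for the glucanase GLUA (Solyc01g008620.3), and none passed, also adjusted over the list alone. Without RNAi_mock replicate 1 they were -1.60 for PR4, -1.40 for PR1B1 and -0.45 for GLUA. Without EV_Ri replicate 3 PR1B1 was at -1.98 and GLUA at -0.36, and PR1B1 at -3.17 without EV_mock replicate 1. The list call was lost without RNAi_mock replicate 1 (-1.18, adjusted p = 0.0987) or EV_Ri replicate 3 (-1.22, adjusted p = 0.0618).

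For the interaction edgeR called 0 genes over all genes, with 746 at an unadjusted p under 0.05 where chance alone gives 1062. DESeq2 called 17 and limma-voom 0, and edgeR called 9 without RNAi_Ri replicate 1. Solyc10g006640.3 (1.61 ± 0.23) and Solyc07g063830.3 (1.5 ± 0.22) had the smallest p (adjusted p = 0.375), followed by Solyc08g007960.1 and Solyc04g082120.3 (-1.71 ± 0.30), both at adjusted p = 0.64. The other lists did not pass and held 0 called genes, with mean log2 differences of 0.33 for jasmonate (camera adjusted p = 0.146), -0.62 for ethylene (0.421), -0.49 for glycoalkaloid synthesis (0.461), -0.26 for iron uptake (0.783), -0.27 for nitrogen uptake (0.608), 0.35 for photosynthesis (0.461) and -0.05 for common symbiosis (0.917). For strigolactone and carotenoid synthesis the mean was -0.14 while the test pointed up (0.904). All genes were negative for glycoalkaloid synthesis (9 of 9) and ethylene (6 of 6), as they were for the markers. Calls appeared for jasmonate without EV_Ri replicate 2 (0.57, adjusted p = 0.00258), ethylene without EV_Ri replicate 1 (-1.19, 0.028), glycoalkaloid synthesis without EV_mock replicate 1 (-1.16, 0.0441) and photosynthesis without RNAi_Ri replicate 3 (0.91, 0.0269; 0.84, 0.0494, with the same 7 genes). None held in the same fits with an estimated correlation (adjusted p = 0.582, 0.575, 0.932 and 0.657, in that order). With all libraries, the ethylene value leaned on RNAi_mock replicate 1, with a list mean of 6.56 (log2 CPM) against 4.82 and 4.62 in its group. The jasmonate value leaned on EV_Ri replicate 1, with 5.01 against 6.17 and 5.90.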

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

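The relabelling test of the mycorrhiza marker interaction and its adjustment over 10 lists, and the set of genes taken from the mean inoculation response over both constructs, were chosen only after the result was seen, while the other tests of this part were planned.

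The mycorrhiza marker list is given here because the effects of the same treatment differed between the 2 constructs by a test of the difference itself, with a mean interaction of -1.12 (log2; camera adjusted p = 7.42e-05, but adjusted p = 0.29 with an estimated correlation), made up of a mean of -0.67 between RNAi_Ri and EV_Ri and one of 0.46 between RNAi_mock and EV_mock (adjusted p = 0.0698). Scaling by library composition and a single inoculated library were weighed for the difference between RNAi_Ri and EV_Ri alone, not for the interaction. Scaling is argued against by a value of -0.68 with total counts alone (main SE 0.24, from the list mean of each library). A single library as the sole source is argued against, since the list stayed lower in RNAi_Ri without any 1 inoculated library. The weakest value was -0.45 with an SE of 0.13 without EV_Ri replicate 2 (camera adjusted p = 0.00258 with the preset correlation). That SE rests on 2 EV_Ri libraries and was 0.24 with all libraries, so this is a weak test. EV_Ri replicate 2 added to the difference between RNAi_Ri and EV_Ri, which was -0.67 with it. With all libraries and an estimated correlation, camera gave that difference an adjusted p of 0.29. The interaction ran from -1.34 to -0.90 as each library was left out. Of 200 relabellings of the libraries, 3 gave a marker interaction as large as the real 1.124 (highest other 1.291), a share of 0.015 for this list alone but of 0.15 adjusted over the 10 lists, so chance is not excluded over all lists, and the 10 splits of the inoculated libraries are too few for a share under 0.05 (real list difference 0.666, highest other 0.514). A smaller colonised share of the RNAi roots may account for the difference between RNAi_Ri and EV_Ri. It cannot account for the 0.46 between the mock groups, which were not inoculated. Such a share would lower genes silent in mock roots by a common factor. Of 88 such genes 87 were lower in RNAi_Ri (median -0.92, or -0.57 without EV_Ri replicate 2). Their SD of 0.39 was 0.83 times their median SE of 0.47 (1.44 times without EV_Ri replicate 1). This is a weak test because that SE includes variation shared between genes. An effect of the construct on the symbiosis genes themselves stays open and untested, as fungal colonisation was not analysed here and the knockdown was not checked.

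The pathogenesis-related list is given for the same reason, a response to inoculation that differed between the 2 constructs by a test of the difference itself, with a mean interaction of -1.70 (SE 0.98 from the list mean of each library; camera adjusted p = 0.00813, but adjusted p = 0.756 with an estimated correlation). Without RNAi_mock replicate 1, whose list mean of 8.34 (log2 CPM) was the highest of the 12 libraries, the value shrank to -1.18 with an SE of 0.88 and no longer passed (adjusted p = 0.0987), and without EV_Ri replicate 3 it was -1.22 (adjusted p = 0.0618), within a range of -2.32 to -1.18 as each library was left out. Given that SE, an effect of RNAi_mock replicate 1 alone and a difference between the constructs cannot be told apart. With the preset correlation, the call was kept when EV_Ri replicate 1 was left out together with RNAi_mock replicate 1. Of 200 relabellings, 19 gave an interaction as large as the real 1.703 (highest other 2.488), so chance is not excluded (share 0.095). Within groups the list mean followed the axis described under the other observations (r = 0.71, rho = 0.76 over 12 libraries; permutation p adjusted over 10 lists 0.054 for r and 0.03 for rho; r = 0.59 without the 2 outermost libraries). That axis was fitted after group means were removed, so it cannot by itself give a difference between groups. RNAi_mock replicate 1 lay at 2.9 on it, in a group that ran from -11.6 to 8.7, which argues against the axis as the source of that library's high list mean. Whether a difference between libraries that the labels do not name contributes was not tested. A biological effect of the construct stays open and untested.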

How the results depend on the processing

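Leaving out RNAi_mock replicate 1 together with EV_Ri replicate 1, leaving out markers with few counts, and leaving out each library with the genes of the full fit kept, were chosen only after the data were seen, and the other alternatives were planned. Depth ran from 17038935 to 20461032 counts and limits genes near 0 counts in mock roots, for which folds are bounds. Among the named genes, 509 comparisons of a called gene with an alternative kept the call and direction and 58 lost the call, and of those not called 472 were unchanged, 21 gained a call and 7 reversed. The reversals were those of PSY3 (0.17 without EV_Ri replicate 2, 0.20 and 0.13 without RNAi_Ri replicate 1 and 2) and DXS2 (0.12 and 0.03 without EV_Ri replicate 2 and 3, 0.22 and 0.12 without RNAi_Ri replicate 1 and 2) between RNAi_Ri and EV_Ri, which ran from -0.71 to 0.20 and from -0.45 to 0.22 as each library was left out and lay near 0 with all 12. The cause of changes was not tested unless stated. The level of the targeted gene, planned as a result, has no value here.

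DESeq2 called 1097 genes for inoculation in EV roots, 816 in RNAi roots, 19 between constructs in mock roots, 8 in inoculated roots and 17 for the interaction, against 596, 352, 0, 0 and 0 with edgeR, and 508 in both constructs in the same direction against 298. In simulated data, which left out variation shared between genes, DESeq2 also made more false calls (51 against 10 for RNAi_Ri and EV_Ri). The 6 EV libraries alone gave 344 calls, and an adjusted p under 0.01 gave 352 in EV and 206 in RNAi roots. Between constructs in mock roots limma-voom called 2 and edgeR 3 without the low-count filter, where edgeR called 0 (596 at an unadjusted p under 0.05). With both doubted libraries left out, 1 gene was called in mock roots, and calls in RNAi roots were 224 higher and 196 lower in place of 267 and 85. Scaling by RLE factors or total counts kept each of these counts within 1.5 times.

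Called lists numbered 2 in EV roots, 2 in RNAi roots, 0 and 1 between constructs in mock and inoculated roots, and 2 for the interaction. With an estimated correlation these became 1, 1, 0, 0 and 0, with the marker means at -0.67 in inoculated roots and -1.12 for the interaction (adjusted p = 0.29 for each). A minimum of 1 CPM gave 1 list in mock roots and 3 in RNAi roots by calling the pathogenesis-related list (adjusted p = 0.0443 for each, but 0.748 with an estimated correlation). Of 60 list calls gained under an alternative, 0 held in the same fit with an estimated correlation (lowest adjusted p = 0.384). With the preset correlation the marker list stayed called in the 4 comparisons where it was called without AMT2.2, STR and RAM2 (means 3.96, 3.02, -0.54 and -0.94). With both doubted libraries left out there were 1 in RNAi roots, 3 in mock roots and 3 in inoculated roots, with genes filtered anew, which can change the members of a list. Photosynthesis was then also called in EV roots and for the interaction (camera adjusted p = 0.00396 and 0.0354, but 0.595 and 0.659 with an estimated correlation).

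As each library was left out, calls ran from 388 (without EV_mock replicate 2) to 644 in EV roots and from 225 (without RNAi_mock replicate 3; 229 without RNAi_mock replicate 2 and 231 without RNAi_Ri replicate 2) to 390 in RNAi roots. Between constructs they ran from 0 to 1 in mock roots (1 without RNAi_mock replicate 1), from 0 to 25 in inoculated roots and from 0 to 9 for the interaction (25 and 9 without RNAi_Ri replicate 1), and the overlap of both responses from 211 to 307. Called lists ran from 2 to 4 in EV roots (4 without EV_Ri replicate 2), 1 to 4 in RNAi roots (1 without RNAi_mock replicate 1, and 4 without EV_Ri replicate 1, RNAi_mock replicate 2 or 3, or RNAi_Ri replicate 1 or 3), 0 to 3 in mock roots (0 without EV_Ri replicate 3, 3 without RNAi_mock replicate 1 or RNAi_Ri replicate 3, and 1 or 2 without any other), 1 to 3 in inoculated roots (3 without EV_Ri replicate 1 or RNAi_Ri replicate 3, and 2 without EV_mock replicate 2, EV_Ri replicate 2 or any 1 RNAi_mock library) and 1 to 3 for the interaction (1 without EV_Ri replicate 3 or RNAi_mock replicate 1). A group of 2 libraries lowers the filter, which then passed 21536 to 21594 genes and added PSBS to the photosynthesis list in all but 2 of these fits. With the 21230 genes kept, calls ran from 387 in EV roots and up to 393 in RNAi roots, and of 51 list calls gained 38 were left and 2 others appeared, with 0 left with an estimated correlation (lowest adjusted p = 0.373). With the preset correlation the marker list stayed called, with means of 5.66 to 6.05, 4.54 to 4.89, -0.84 to -0.45 and -1.34 to -0.90 for EV roots, RNAi roots, inoculated roots and the interaction. The last 2 of these calls did not hold with an estimated correlation (adjusted p = 0.29 for each with all libraries).

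Libraries with the same replicate number were not paired: of 18 such pairs 4 correlated above 0.1 and 9 below -0.1, and in 9 of 36 comparisons a library correlated best with its own number. With the replicate number as a block, edgeR called 474 and 278 genes for inoculation in EV and RNAi roots and 0 for each comparison between constructs and the interaction (596, 739 and 746 genes had an unadjusted p under 0.05 without the block), and 248 in both constructs. Under the block 7 calls of named genes did not pass, with adjusted p of 0.0802 for DXS2, 0.0647 for NIR, 0.059 for GA20OX1 and 0.138 for GA3OX1 in EV roots, and 0.0809 for CCD1A, 0.0517 for NIR and 0.15 for Solyc12g042960.2 in RNAi roots.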

Other observations

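The tests of the replicate number and of green tissue against the within-group axis, the splits for the comparisons between constructs and for the interaction, and the gene set from the mean inoculation response and its values as each library was left out were chosen only after a result was seen. Lists too short for a list test held genes of phosphate supply, sugar, gibberellin and phenylpropanoids. PT1 (Solyc09g090070.2), a phosphate transporter that takes up phosphate from the soil, stood at 269 ± 69.9 CPM in EV_mock, 543 ± 117 in EV_Ri, 354 ± 105 in RNAi_mock and 417 ± 15.9 in RNAi_Ri (SD, n = 3). Its response was 1.01 ± 0.26 in EV roots (SE; edgeR adjusted p = 0.0728 over all genes, or 0.0489 without EV_mock replicate 1 and 0.027 without RNAi_mock replicate 1) and 0.24 ± 0.25 in RNAi roots (adjusted p = 0.731). Adjusted over the list alone, which has 2 genes, it passed in EV roots (adjusted p = 0.00485). The interaction of -0.77 ± 0.36 did not pass. PT7 (Solyc09g066410.2), of the same family, had -0.52 ± 0.56 and -1.01 ± 0.57. LIN6 (Solyc10g083290.2), a cell wall invertase, measured 33.8 ± 2.79 and 73.3 ± 35.3 CPM in EV_mock and EV_Ri (1.12 ± 0.43, adjusted p = 0.295) and 61.2 ± 27.1 and 49 ± 19.6 CPM in RNAi_mock and RNAi_Ri (-0.32 ± 0.43, adjusted p = 0.795; 0.03 without RNAi_mock replicate 1).

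The gibberellin synthesis genes that rose in EV roots did not pass over all genes in RNAi roots, where GA3OX1 (Solyc06g066820.3) went from 5.44 to 30.9 CPM (2.51 ± 0.68, edgeR adjusted p = 0.136, or 0.021 without EV_mock replicate 1) and GA20OX1 (Solyc03g006880.3) from 1.59 to 4.68 CPM (1.56 ± 0.52, adjusted p = 0.241), though both passed adjusted over the list alone (0.0156 and 0.0239). Their interactions, -0.57 ± 0.92 and -1.11 ± 0.72, did not pass, and were -1.91 and -1.76 without EV_mock replicate 1. The other gibberellin genes, CPS (Solyc06g084240.2; 1.98 ± 0.96 in EV and 1.35 ± 0.94 in RNAi roots, with 3.43 without EV_mock replicate 1 and 0.22 without RNAi_Ri replicate 3) and GA20OX3 (Solyc11g072310.2; -0.41 ± 0.33 and 0.44 ± 0.33, the latter at -0.05 without RNAi_Ri replicate 1), did not pass in either. Of the phenylpropanoid genes 0 of 3 passed in either construct, also adjusted over the list alone, with Solyc09g007910.3, listed as a phenylalanine ammonia-lyase, at 1170 ± 135 CPM in EV_mock and 1090 ± 107 CPM in EV_Ri. Of the sugar genes 0 of 4 passed, also adjusted over the list alone.

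Genes raised by inoculation tended to have lower values in RNAi_Ri than in EV_Ri beyond the marker list, although none was called in that comparison. In the mean response over both constructs edgeR called 719 genes higher, and 577 of them (80.3%) had lower fitted values in RNAi_Ri than in EV_Ri, with a median log2 difference of -0.51, against 47.8% of the 20092 genes called in neither direction and 63.2% of the 419 called lower (median -0.09). As a hypothesis, the genes raised by inoculation may be attenuated as a whole with the RNAi construct. In 30 simulations without a construct effect 47.2% to 53.8% were lower, although these drew genes independently and leave out variation shared between genes. A weaker response in both directions would leave the genes called lower at higher values in RNAi_Ri. Instead 63.2% of them had lower values (camera p = 0.0968, unadjusted, with an estimated correlation), so the hypothesis does not extend to them. With the inter-gene correlation estimated, camera gave the 719 raised genes an unadjusted p of 0.0239 in RNAi_Ri against EV_Ri and 0.0285 for the interaction. Neither stayed under 0.05 without EV_Ri replicate 1, where the camera test gave 0.166 and 0.133, or without RNAi_Ri replicate 3, where it gave 0.119 and 0.095. That of the interaction was 0.0573 without RNAi_mock replicate 3. As each library was left out, 75.5% to 83.4% of the genes were lower in RNAi_Ri. Per library, the 719 genes held 4.14 ± 0.993% of counts in EV_Ri and 3.05 ± 0.202% in RNAi_Ri (SD, n = 3; exact permutation p = 0.1, the smallest possible), and 1.28 ± 0.0973% and 1.4 ± 0.088% in EV_mock and RNAi_mock. Their mean log2 CPM differed by -0.457 (exact permutation p = 0.2). Without EV_Ri replicate 2 the difference was -0.293 in mean log2 CPM and -0.547 in percent of counts, with a median over the genes of -0.32.

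Genes called higher in EV roots often had neighbours that were also called. By the order of identifiers, 48 pairs of adjacent genes were both higher, where 1000 random placements of the 484 genes gave a mean of 11 and a highest of 29. Runs of adjacent called genes held 89 genes, 5 runs had at least 3, and the longest had 5. Neighbouring genes that respond together, such as tandem copies, are a candidate explanation for the 48 pairs, and reads shared between near-identical copies were not tested and stay possible.

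Libraries of EV_mock, EV_Ri and RNAi_Ri were spread along an axis fitted to all groups together. It held 38.2% of the variance left after group means were removed. The RNAi_mock libraries were little spread along it, from -11.6 to 8.7. Its full range was from -71.4 for EV_Ri replicate 1 to 50.1 for EV_mock replicate 1. A batch that follows the replicate number is argued against, since these same-numbered libraries had a correlation of -0.57 across genes, the lowest of 18 same-numbered pairs. Library size stays open, with r = 0.47 within groups (permutation p = 0.134; rho = 0.51, permutation p = 0.12; r = 0.49 without the 2 outermost libraries). A share of green tissue also stays open, as all 7 photosynthesis genes moved against the axis, but their mean did not pass (r = -0.71, rho = -0.63; permutation p adjusted over 10 lists 0.124 for r and 0.152 for rho; r = -0.69 without the 2 outermost libraries). The lists closest to the axis were glycoalkaloid synthesis (9 of 9 genes positive) and nitrogen uptake (4 of 5), with the list members among the genes that define it, and the labels name no group that gives a biological explanation.

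Other splits of the same libraries were counted for each number of called genes. For inoculation in EV roots the real split called 596 genes and 2 of 10 splits called at least as many, the other being EV_mock replicate 1 with EV_Ri replicates 2 and 3 against the rest, with 1446 calls. For inoculation in RNAi roots the real split called 352 and the highest other 1. In mock roots the constructs gave 0 calls and the highest other split 22, and in inoculated roots 0 and 724, the latter for EV_Ri replicate 1 with RNAi_Ri replicates 1 and 2 against the rest. In each of these comparisons 10 splits are too few for a share under 0.05. For the interaction, 40 of the 200 relabellings were drawn, and the highest had 3799 calls against 0 for the real labels. Where the real count was 0, the splits say nothing about chance. The splits with 1446, 724 and 3799 calls were those of their comparison closest to the within-group axis (R squared 0.833, 0.782 and 0.568). The axis is the largest component of the spread within groups of these same libraries. A split along it is therefore likely to call many genes, and the match is not separate evidence for a structure of the samples. In mock roots and in RNAi roots the highest other splits, with 22 calls and 1 call, were not the closest to the axis (R squared 0.355 and 0.404, against 0.607 and 0.575 for the closest, which called 0), so the match was not seen in those comparisons.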
